A study of Mus musculus with 6 samples.

How the data were processed

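Liver RNA of C57BL/6J mice was measured on 6 Illumina expression bead arrays, 1 array for each combination of 3 diet arms and 2 times of day. Each array was hybridised with RNA pooled from 4 mice. The arms were regular chow (RC), high-fat diet with vehicle (HFD) and high-fat diet with nobiletin (NOB), a polymethoxylated flavone of citrus peel known as an agonist of the ROR nuclear receptors. Nobiletin was given by mouth at 200 mg/kg every other day for 10 weeks. Livers were taken at 18 weeks of age, under 12 h of light and 12 h of darkness with free access to food, at zeitgeber time (ZT) 2 and ZT14. The sex of the mice is not given in the sources used here. RNA was extracted with RNeasy kits and labelled with biotin.

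The deposited non-normalized table gave an intensity for each of 45281 probes, as the average bead signal, and a detection p value from the negative-control probes of the same array. The medians of these intensities differed between arrays and none lay below 37.7, so neither background subtraction nor scaling had been applied to them. The authors' processed matrix gave a second intensity per probe on a linear scale. The software named in the submitters' processing notes is GenomeStudio, and its version and the normalization option are not given in the sources used here. From the values themselves, the authors' intensities were background-subtracted and quantile normalized. The median of the authors' values was 3.5 in RC at ZT2, 3.5 in HFD at ZT2, 3.5 in NOB at ZT2, 3.5 in RC at ZT14, 3.5 in HFD at ZT14 and 3.5 in NOB at ZT14, and the lowest value of each column was -15.9. The scale of these values was settled as linear and their columns were matched to the arrays. The amount subtracted from each array and the centring of each array before it was equalised with the others remain unknown. Over 11487 probes detected on every array, each processed column correlated with its own array at r = 0.966 to 0.984 after the mean of each probe was removed, and the highest correlation with any other array was 0.349.

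The non-normalized intensities were corrected and normalized with the neqc method of limma 3.58.1 in R 4.3.3. This method models the background from the detection p values, adds an offset of 16, applies quantile normalization and takes log2. Probes were kept when their detection p lay under 0.01 on at least 2 of the 6 arrays, which left 14416 probes. Gene symbols came from the probe table of the platform, and 34807 probes matched a gene identifier of the GRCm38.p6 annotation table, with 0 symbols changed by it. In all, 34885 probes carried 1 symbol, 18 carried several and 10378 were not listed. Of the detected probes, 12485 were named and 1931 were not and were left out. Of the probes of a gene, the brightest over all 6 arrays stood for it, which applied to 2844 genes with several detected probes. This gave 8561 genes, of which 211 had only clone or predicted-locus names. Positions in the genome were not used. A gene detected on no array of a group has no measured level there, so its fold is given as a lower bound against the background of those arrays.

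Precision was set by the number of arrays, which is small. Detection and signal over background stand in for depth: 28.1% to 32.0% of the probes were detected on each array. With 1 array per group, a difference within a time has no replicate check and was given as a value without a test. Differences between arms were tested over both times with limma, with arm and time as additive terms, which left 2 residual degrees of freedom to which the moderation across genes added 4.83. In this model, a difference between arms that depends on the time counts as residual spread. Tests were two-sided with a Benjamini-Hochberg false discovery rate of 0.05 over the 8561 genes, for HFD minus RC, NOB minus HFD, NOB minus RC and ZT14 minus ZT2. Data were simulated with normal noise, independent between genes and arrays, and with no arm difference that depended on the time. The pipeline was tested on these data, with 200 changed genes of 8561, so its rates may not hold for real pools. It recovered 72% of 2-fold and 99% of 4-fold changes for HFD minus RC, 57% and 99% for NOB minus HFD, and 86% and 98% for ZT14 minus ZT2, with 10, 5 and 10 false calls.

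Before the data were examined, 32 gene lists were fixed. They covered clock genes high at dusk, clock genes high at dawn, nuclear receptors of the ROR family, fatty acid synthesis, cholesterol synthesis and uptake, bile acid synthesis and transport, fatty acid oxidation and PPAR-alpha targets, lipid droplet and PPAR-gamma targets, glucose metabolism and insulin response, drug metabolism (CAR and PXR targets), aryl hydrocarbon receptor targets, NRF2 targets, heat shock, the unfolded protein and integrated stress response, the acute phase, the interferon response, oxidative phosphorylation, amino acid breakdown and the urea cycle, male-biased liver genes, female-biased liver genes, cell division and cytosolic ribosomal proteins. Markers of Kupffer cells and macrophages, antigen presentation, lymphocytes, neutrophils, stellate cells and fibrosis, endothelium, cholangiocytes, red blood cells, adipocytes and exocrine pancreas completed them. Lists with at least 3 measured members, 26 in number, were tested with camera of limma at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Adjustment ran over 78 tests, which are 26 lists in 3 contrasts. Within a time or an arm, the median of a list was ranked among the medians of 10000 random lists matched on expression in 20 bins.

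The choice of genes to name was fixed at the same time. For HFD minus RC and NOB minus HFD these were the 8 highest and the 8 lowest genes among those at least 1.5-fold apart the same way at both times, and up to 3 members of each list with the largest mean difference. For ZT14 minus ZT2 they were the 8 highest and the 8 lowest among genes at least 2-fold apart the same way in all 3 arms, every measured clock gene and up to 3 members of the other lists. No gene was named by rank for NOB minus RC. Genes named outside this choice are given as chosen after their values were seen. Shares of genes carry exact Clopper-Pearson intervals at 95%, which cover counting error only, and genes are not independent replicates.

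The alternatives fixed with the design were the authors' values (log2 after adding 16, with values under 0 set to 0), background correction with an offset of 50, no background correction, median scaling, no detection filter, detection on all 6 arrays, the mean of a gene's probes, leaving out each array in turn, moderation with an intensity trend, only the 2 arms compared, no term for time or for arm, and other fold thresholds. Testing every detected probe and leaving out skeletal muscle genes were added after seeing the data. The 1931 detected probes without a single gene name entered only the test of every detected probe, and 0 columns of the deposited tables were unused.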

Results

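Transcripts were measured in 6 pools of mouse liver RNA, 4 mice to a pool and 1 array to a pool. The pools came from mice on regular chow (RC), on a high-fat diet with vehicle (HFD) and on a high-fat diet with the citrus flavone nobiletin (NOB), each taken at ZT2, 2 h after lights on, and at ZT14, 2 h after lights off. The series was made to follow the effects of the diet and of nobiletin on the liver transcriptome. There were no replicates, so differences within a time had no replicate check, and the number of arrays limits the precision of every value. Of 45281 probes, 13198 were detected in RC at ZT2, 14470 in HFD at ZT2, 14039 in NOB at ZT2, 12712 in RC at ZT14, 13134 in HFD at ZT14 and 12885 in NOB at ZT14. Median raw signals lay between 57.5 and 62.4, and the pools correlated with each other at r = 0.960 to 0.987 across 8561 genes, which are not independent replicates.

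The comparison of the high-fat diet with chow asked which liver genes followed the diet. On the high-fat diet, 385 genes rose and 200 fell over both times, and 304 of these 585 differed by at least 2-fold. Cyp2b9, a cytochrome P450 of the drug-metabolizing CYP2B family, was 53.4-fold higher (log2 difference 5.74 ± 0.14 SE, adjusted p = 1.58e-05), and Apoa4, an apolipoprotein of lipid absorption and secretion, was 43.8-fold higher (5.45 ± 0.25, adjusted p = 0.000371). The HFD arrays had Apoa4 and the thiolase gene Acaa1b near the top of the scale, at 14.09 and 14.30 on average against a highest level of 14.59, where differences are compressed. Fgf21, a fasting-induced hepatokine that was undetected in chow, was at least 13.7-fold higher, and Cidec, a protein of lipid droplets, lay at 3.57 ± 0.28. The steroid dehydrogenase gene Hsd3b5 was lower (-4.84 ± 0.65, adjusted p = 0.0112), and the fatty acid hydroxylase gene Cyp4a12b was lower (-4.26 ± 0.70, adjusted p = 0.0205). The fixed choice also held Ly6d at 4.46, Wfdc2 at 4.37 and Rgs16 at 4.34, which passed as higher. Serpina4-ps1 at -3.14, Eif4ebp3 at -3.08, C8b at -2.73 and Slc13a2 at -2.59 passed as lower. Hsd3b5, Cyp4a12b, Asns, Serpina4-ps1, Eif4ebp3 and Slc13a2 were detected on 1 of the 2 HFD arrays. Cidec, Pnpla3, Trem2 and Ly6d were detected on 1 of the 2 RC arrays, so the sizes in both sets of genes rest partly on background.

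Lipid genes lay higher. In the lipid droplet and PPAR-gamma list, 6 of 12 measured members rose and 0 fell, or 8 when adjusted over the list alone. Plin4, a lipid droplet coat protein, stood at 3.28 ± 0.52 beside Cidec at 3.57 ± 0.28. The list lay above other genes (camera adjusted p = 2.28e-07, and adjusted p = 0.556 with an estimated correlation). Of 18 fatty acid synthesis genes 6 rose and 0 fell, or 11 adjusted over the list alone. Among them were the pyruvate kinase gene Pklr at 1.69 ± 0.16, the elongase Elovl5 at 1.61 ± 0.28 and Pnpla3 at 1.19 ± 0.22 (camera adjusted p = 4.73e-05, and adjusted p = 0.556 with an estimated correlation). In the fatty acid oxidation and PPAR-alpha list, 4 of 17 rose and 0 fell, or 6 adjusted over the list alone. Fgf21 was 1 of them, as were the peroxisomal division gene Pex11a at 1.41 ± 0.16 and the peroxisomal thiolase Acaa1b at 0.99 ± 0.15 (camera adjusted p = 4.36e-05, and adjusted p = 0.556 with an estimated correlation). Cholesterol synthesis and uptake moved the other way: the sterol reductase Tm7sf2 fell (-0.90 ± 0.19), as the single call among 18 genes, or 1 of 3 adjusted over the list alone, while Sqle at -0.71 and Cyp51 at -0.63 did not pass. That list lay below other genes (median -0.45, camera adjusted p = 0.000206, and adjusted p = 0.605 with an estimated correlation).

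Genes that are higher in male liver lay lower on the high-fat diet, with the largest median by size of any list over both times. Of 9 measured male-biased genes 7 fell and 0 rose, or 8 adjusted over the list alone, and their median was -2.04 (camera adjusted p = 2.28e-07, and adjusted p = 0.556 with an estimated correlation). Hsd3b5, Cyp4a12b and Cyp4a12a at -2.37 ± 0.52 led them. Of 5 measured female-biased genes 2 rose, or 3 adjusted over the list alone, namely Cyp2b9 and the acyl-CoA thioesterase Acot3 at 1.95 ± 0.37, and Cyp17a1 at 1.02 did not pass. The female-biased list lay above other genes (median 1.02, camera adjusted p = 0.0121, and adjusted p = 0.611 with an estimated correlation). This call ended without the RC array of ZT14 (adjusted p = 0.199) and without the HFD array of ZT14 (adjusted p = 0.0800). Its range was 0.000133 to 0.611 over the alternatives. Within the times the female-biased median was 0.47 at ZT2 and 2.31 at ZT14. The Cyp2b and Cyp4a12 genes are near-identical within their families, and cross-hybridisation of their probes was not tested.

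Drug metabolism genes, targets of the xenobiotic receptors CAR and PXR, went both ways. Of 18 measured, 2 rose and 6 fell, or 5 and 8 adjusted over the list alone: Cyp2b9 and Cyp2b13 (at least 12.9-fold) were higher, and Cyp2b10 at -3.34 ± 0.40 and Cyp2c54 at -2.84 ± 0.32 were lower. The list as a whole was not called (camera adjusted p = 0.339, and adjusted p = 0.622 with an estimated correlation), and its median of -0.19, its mean of 0.01 and a test direction of lower differed in sign. Cyp1a2, which metabolizes caffeine and is a target of the aryl hydrocarbon receptor, fell (-1.94 ± 0.22) as the 1 call among 3 receptor targets, both over all genes and adjusted over the list alone. Nqo1 at 0.47 and Ugt1a6a at 0.16 did not pass, probes of Ugt1a6a differed in sign, and the list was not called (median 0.16, mean -0.44, test direction lower, camera adjusted p = 0.724, and adjusted p = 0.898 with an estimated correlation). Among 9 NRF2 targets the sulfiredoxin gene Srxn1 rose (1.01 ± 0.21), with 2 calls adjusted over the list alone. The glutathione transferase genes Gsta1 at 2.28 and Gsta2 at 0.91 did not pass (camera adjusted p = 0.0986 for the list, and adjusted p = 0.609 with an estimated correlation). The 3 probes of Gsta1 ranged from 0.28 to 2.43.

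Stress-response genes lay lower. In the unfolded protein and integrated stress response list 6 of 17 members fell and 1 rose, or 11 and 1 adjusted over the list alone. Lower were the asparagine synthetase gene Asns at -2.57 ± 0.51 and the endoplasmic reticulum genes Creld2 at -2.53 ± 0.31 and Sdf2l1 at -2.07 ± 0.41. The list lay below other genes (median -0.78, camera adjusted p = 2.34e-05, and adjusted p = 0.556 with an estimated correlation). Of 7 heat shock genes 1 fell, the chaperone gene Hsph1 (-1.84 ± 0.38), or 6 adjusted over the list alone. Hsp90aa1 at -1.08 and Dnajb1 at -0.88 did not pass (camera adjusted p = 0.000721, and adjusted p = 0.605 with an estimated correlation). Amino acid breakdown and urea cycle genes fell in 4 of 11 cases and rose in 0, or 5 adjusted over the list alone. They included the urea cycle enzymes Cps1 at -1.41 ± 0.19 and Asl at -0.82 ± 0.15 and the histidine-degrading Hal at -0.77 ± 0.15 (camera adjusted p = 0.000149, and adjusted p = 0.556 with an estimated correlation). For 11 cytosolic ribosomal proteins 0 members passed limma at either adjustment. Rpl13a lay at -0.55, Rps6 at -0.39 and Rps3 at -0.31, and the list lay below other genes by a small amount (median -0.20, camera adjusted p = 0.0256, and adjusted p = 0.556 with an estimated correlation). That call ended without the HFD array of ZT14 (adjusted p = 0.0553), without the HFD array of ZT2 (adjusted p = 0.0588) and without the RC array of ZT2 (adjusted p = 0.165). Its range was 0.00133 to 0.556 over the alternatives.

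Genes of macrophages and of antigen presentation were higher on the high-fat diet. All 6 measured antigen presentation genes rose, also when adjusted over the list alone. The MHC class II genes H2-Ab1 at 1.53 ± 0.27 and H2-Eb1 at 1.48 ± 0.30 and the invariant chain Cd74 at 1.39 ± 0.23 led them (camera adjusted p = 2.24e-05, and adjusted p = 0.605 with an estimated correlation). Among 14 Kupffer cell and macrophage markers 4 rose and 0 fell, or 8 adjusted over the list alone. Gpnmb, a glycoprotein of lipid-laden macrophages that was undetected in chow, was at least 7.11-fold higher, and Lgals3 at 2.11 ± 0.23 and Trem2 at 1.45 ± 0.16 were higher too (camera adjusted p = 5.58e-06, and adjusted p = 0.605 with an estimated correlation). Of 10 stellate cell and fibrosis markers 3 rose and 0 fell, or 4 adjusted over the list alone. The metalloproteinase inhibitor Timp1 was at least 2.95-fold higher and lumican, Lum, lay at 0.85 ± 0.16, while the collagen gene Col1a1, undetected in chow, was at least 1.19-fold higher and did not pass. The stellate list had a median of 0.48, or 0.43 with 2 undetected members at their bounds (camera adjusted p = 0.00338, and adjusted p = 0.556 with an estimated correlation), and its call ended without the RC array of ZT2 (adjusted p = 0.0881). Its range was 5.46e-05 to 0.556 over the alternatives. Interferon response genes rose in 2 of 11 cases and fell in 0, or 3 adjusted over the list alone. The guanylate-binding proteins Gbp2 and Gbp3 stood at 1.15 ± 0.18 and 1.01 ± 0.19, while Rsad2 at 0.76 did not pass (camera adjusted p = 0.0256, and adjusted p = 0.605 with an estimated correlation). That call ended without the RC array of ZT14 (adjusted p = 0.228) and without the HFD array of ZT14 (adjusted p = 0.140). Its range was 0.00303 to 0.605 over the alternatives. Of 10 cell division genes Mcm2, a subunit of the replicative helicase, rose by at least 1.99-fold, or 7 rose adjusted over the list alone, while Cdc20 at 1.55 and Mcm5 at 1.31 did not pass. The median of the division list was 0.92, or 0.72 with 3 undetected members at their bounds (camera adjusted p = 0.000468, and adjusted p = 0.609 with an estimated correlation). Within the times it was 0.32 at ZT2 and 1.42 at ZT14, where Mcm5 lay at 0.26 and 2.36. Medians also lay lower at ZT2 than at ZT14 for antigen presentation (0.83 and 1.85), macrophage markers (0.53 and 1.15) and the interferon response (0.23 and 0.66), differences that were not tested.

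In bile acid, glucose and acute phase lists members passed both ways. The bile acid list had 1 member that rose and 2 that fell of 13, or 1 and 4 adjusted over the list alone. These were the oxysterol hydroxylase gene Cyp7b1 at -2.08 ± 0.31, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.80 ± 0.17 and the phospholipid transporter Abcb4 at 0.76 ± 0.15 (camera adjusted p = 0.339, and adjusted p = 0.670 with an estimated correlation). In glucose metabolism and insulin response 2 of 17 rose and 3 fell, or 3 and 3 adjusted over the list alone. Examples were the growth factor binding protein Igfbp2 at -2.47 ± 0.16, the insulin receptor substrate Irs2 at -1.02 ± 0.18 and Insig2 at 1.03 ± 0.20. The glucose list was not called (median 0.11, mean -0.06, test direction lower, camera adjusted p = 0.949, and adjusted p = 0.952 with an estimated correlation). Acute phase genes included Lcn2, which encodes lipocalin, at 2.24 ± 0.20, and the hepcidin gene Hamp at -1.61 ± 0.25 and Saa3 at -0.85 ± 0.18. They were 1 call higher and 2 lower of 16, or 2 and 2 adjusted over the list alone (median -0.06, mean 0.02, test direction lower, camera adjusted p = 0.993, and adjusted p = 0.993 with an estimated correlation). None of 22 oxidative phosphorylation genes passed limma at either adjustment, with Cycs at 0.35, Sdhd at -0.26 and Ndufb5 at -0.23, and probes of Cycs differed in sign (camera adjusted p = 0.799, and adjusted p = 0.898 with an estimated correlation).

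Markers of other cells were mixed. No endothelial marker of 8 passed limma at either adjustment, with Lyve1 at 0.77 (camera adjusted p = 0.134, and adjusted p = 0.671 with an estimated correlation), nor did any of 3 red blood cell markers, with Alas2 at -0.32 (camera adjusted p = 0.680, and adjusted p = 0.894 with an estimated correlation). Of 3 exocrine pancreas markers the elastase gene Cela2a fell by at least 1.30-fold, also adjusted over the list alone, and Cela1 lay at -0.71. The median of the pancreas list was -0.71, or -0.38 with the undetected member at its bound (camera adjusted p = 0.196, and adjusted p = 0.671 with an estimated correlation). Lists with fewer than 3 measured members were not tested: the neutrophil genes S100a8 at 1.78 and S100a9 at 1.06, the lymphocyte genes Ccl5 at 0.83 and Cd79b, at least 1.11-fold higher, the cholangiocyte gene Sox9 at -0.55, the adipocyte genes Adipoq at -0.95 and Lep at -0.16, and Rora, the measured ROR receptor, at -0.30 did not pass limma. Skeletal muscle genes, listed after the value of Acta1 was seen, had a median difference of -1.94 at ZT14 and of 0.09 at ZT2 over 14 measured members.

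The test over both times used limma, and the 2072 genes at an unadjusted p under 0.05 stand beside the 585. At single times without a test, 410 genes were at least 1.5-fold higher and 213 at least 1.5-fold lower at both ZT2 and ZT14, against 13 in opposite directions, and the differences at both times correlated at r = 0.66 across genes. Each gene named as passing for the diet or for nobiletin differed the same way at both times. The 585 calls became 42 without the HFD array of ZT2, 32 without that of ZT14 and 169 without the RC array of ZT14. Of the 55 named genes that passed, 37 no longer passed without the HFD array of ZT2, 44 without that of ZT14, 27 without the RC array of ZT14, 9 without the RC array of ZT2 and 2 without either NOB array, with 0 turned in sign.

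The comparison of nobiletin with vehicle on the high-fat diet asked what the compound altered. In the nobiletin pools 11 genes were lower and 3 higher than in the vehicle pools. Gpnmb fell by 2.52 on the log2 scale (± 0.14 SE, adjusted p = 0.00417), which is 5.75-fold, at -2.52 at ZT2 and -2.53 at ZT14. Lcn2 was 5.51-fold lower (-2.46 ± 0.20, adjusted p = 0.0144), the ubiquitin-like modifier Ubd 5.33-fold lower (-2.41 ± 0.21, adjusted p = 0.0149), and Timp1 at least 3.11-fold and Sdcbp2 at least 3.23-fold lower, both undetected under nobiletin. The other probe of Sdcbp2 lay at -0.999, which is less than the bound. Higher were Cyp1a2, 3.94-fold (1.98 ± 0.22, adjusted p = 0.0321), Igfbp2, 3.60-fold (1.85 ± 0.16, adjusted p = 0.0144), and the uridine phosphorylase gene Upp2, 3.25-fold (1.70 ± 0.16, adjusted p = 0.0162).

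The acute phase glycoprotein Orm2 fell as well (-1.35 ± 0.15, adjusted p = 0.0318). Chosen after their values were seen, the other 5 calls were Anxa2, a membrane-binding annexin, at -2.06, the calcium-binding S100a11 at -1.91, the carbonyl reductase Cbr3 at -1.80, the kinase Limk1 at -1.34 and the sulfate transporter Slc13a4 at -1.33. Other genes far apart at both times did not pass: Ly6d at -3.19 (adjusted p = 0.0518), Cidea at -2.56, Cyp2b13 at -2.26, Gsta1 at -2.20, Cyp2b10 at 2.06, Cyp2c54 at 1.91, Erdr1 at 1.37, Sult2a8 at 1.15 and the scavenger receptor Cd163 at 1.14.

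**Figure D1:**
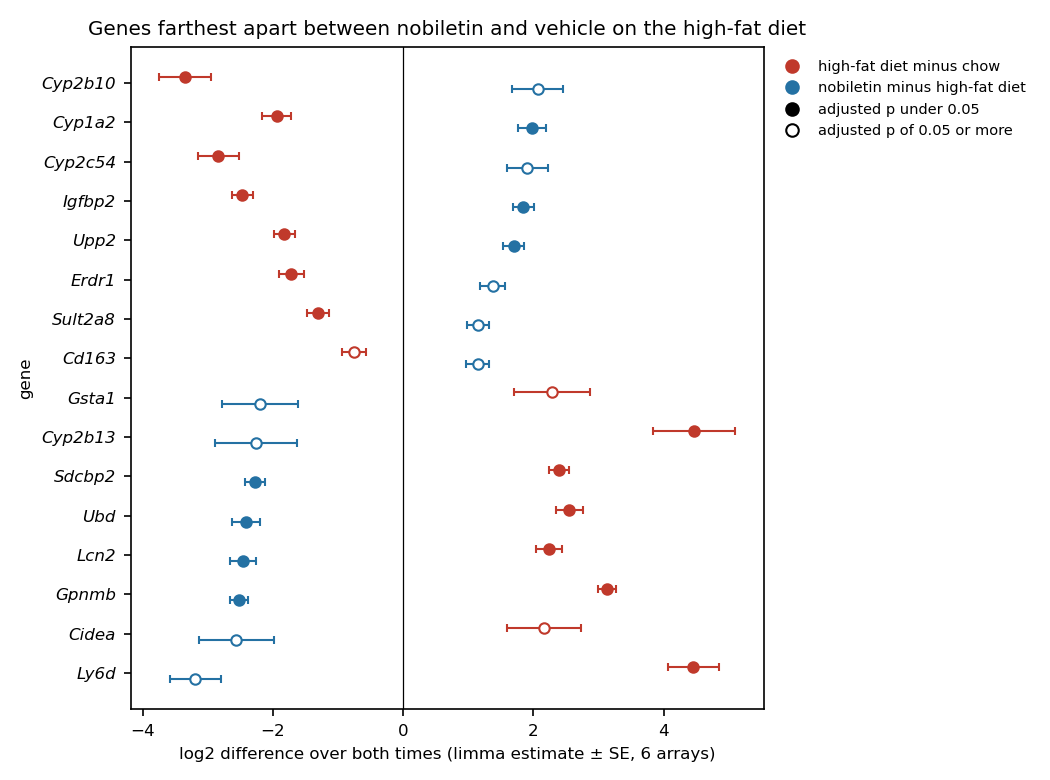
The horizontal axis gives the log2 difference over both times, with points for limma estimates and bars for their SE over 6 arrays, for the 8 highest and 8 lowest genes between nobiletin and vehicle on the high-fat diet, which are listed on the vertical axis. Filled points passed an adjusted p of 0.05. Lcn2 lay at 2.24 for the diet (red) and -2.46 for nobiletin (blue), and every gene drawn had opposite signs. The genes were chosen by their nobiletin difference, which shares the HFD arrays with the diet difference. Opposite signs are therefore likely without an effect. Genes undetected in a group, such as Gpnmb on chow, stand at their fitted values.

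Cholesterol synthesis and uptake lay higher under nobiletin. All 18 measured members had positive differences (median 0.58), none passed limma over all genes, where 753 genes lay at an unadjusted p under 0.05, and 10 passed adjusted over the list alone. Examples are the sterol demethylation genes Msmo1 at 0.88 and Cyp51 at 0.76 and the cyclase Lss at 0.81. The list was called (camera adjusted p = 1.92e-11, and adjusted p = 0.556 with an estimated correlation). Bile acid genes lay higher with 0 of 13 calls at either adjustment, Cyp7b1 at 0.83, Cyp27a1 at 0.61 and the bile salt export pump Abcb11 at 0.54 (camera adjusted p = 0.00171, and adjusted p = 0.556 with an estimated correlation). That call ended without the HFD array of ZT14 (adjusted p = 0.108) and without the NOB array of ZT14 (adjusted p = 0.134). Its range was 7.92e-05 to 0.556 over the alternatives. The bile acid median was 0.02 at ZT2 and 0.35 at ZT14. Amino acid breakdown and urea cycle genes lay higher with 0 of 11 calls, or 1 adjusted over the list alone. Hpd lay at 0.71, Cps1 at 0.65 and Asl at 0.48 (camera adjusted p = 0.000440, and adjusted p = 0.556 with an estimated correlation). The 7 heat shock genes, with 0 calls at either adjustment and Hsph1 at 0.58, Dnajb1 at 0.41 and Hspa8 at 0.32, lay higher (camera adjusted p = 0.0256, and adjusted p = 0.611 with an estimated correlation). Their median was 0.54 at ZT2 and -0.10 at ZT14, so it was not higher at ZT14. The call ended without the HFD array of ZT2 (adjusted p = 0.207) and, with its direction turned, without the NOB array of ZT2 (adjusted p = 0.598). Its range was 6.69e-06 to 0.611 over the alternatives.

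Lipid droplet, antigen presentation and matrix genes lay lower under nobiletin. In the lipid droplet and PPAR-gamma list 0 of 12 passed over all genes and 4 were lower adjusted over the list alone. Cidea lay at -2.56, Cidec at -1.96 and the receptor gene Pparg itself at -1.40 (median -0.63, camera adjusted p = 1.41e-06, and adjusted p = 0.556 with an estimated correlation). The lipid droplet median was -0.83 at ZT2 and -0.14 at ZT14, so it rests mostly on the ZT2 pools. The 6 antigen presentation genes were all lower adjusted over the list alone and 0 passed over all genes. H2-Eb1 lay at -1.25, H2-Ab1 at -1.02 and Cd74 at -0.98 (camera adjusted p = 3.51e-07, and adjusted p = 0.566 with an estimated correlation). Stellate cell and fibrosis markers had 1 call of 10, Timp1, and 2 adjusted over the list alone. The actin gene Acta2 lay at -1.13, whose probes differed in sign, and Col1a1 was at least 1.25-fold lower without passing (median -0.41, or -0.35 with 3 undetected members at their bounds, camera adjusted p = 1.37e-05, and adjusted p = 0.556 with an estimated correlation). Kupffer cell and macrophage markers had 1 call of 14, Gpnmb, and 3 adjusted over the list alone, and 6 of them lay above zero and 8 below. Trem2 lay at -1.23 and Lgals3 at -1.13 (median -0.07, camera adjusted p = 0.0256, and adjusted p = 0.671 with an estimated correlation). Without the NOB array of ZT2 that macrophage call ended and its direction turned (adjusted p = 0.825), and it ended without the HFD array of ZT14 (adjusted p = 0.130). Its range was 1.40e-05 to 0.825 over the alternatives. Cell division genes had 0 calls of 10, or 2 adjusted over the list alone. Cdc20 lay at -1.38, Birc5 at -0.94 and Mcm5 at -0.84 (camera adjusted p = 0.000108, and adjusted p = 0.605 with an estimated correlation). The division median was -0.11 at ZT2 and -1.07 at ZT14, and the list call ended without the HFD array of ZT14 (adjusted p = 0.524). Its range was 1.79e-11 to 0.605 over the alternatives.

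The acute phase list, with Lcn2 and Orm2 as 2 calls of 16 and Saa1 at -1.17, had 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00171, and adjusted p = 0.556 with an estimated correlation). The 3 red blood cell markers, with Slc4a1 at least 1.16-fold lower, Hba-a1 at -0.53 and Alas2 at -0.42, gave 0 calls at either adjustment and a median of -0.53 (-0.18 at ZT2 and -0.80 at ZT14), or -0.42 with the undetected member at its bound (camera adjusted p = 0.0220, and adjusted p = 0.605 with an estimated correlation). That call ended without the HFD array of ZT14 (adjusted p = 0.530) and without the NOB array of ZT14 (adjusted p = 0.0964). Its range was 0.000312 to 0.605 over the alternatives. Lists without a call were fatty acid synthesis (median 0.07), with Pnpla3 at -0.61, fatty acid oxidation and PPAR-alpha targets (-0.08), with Pdk4 at -0.65, glucose metabolism and insulin response (0.06), with Igfbp2 as its call, NRF2 targets (-0.10), with Gsta2 at -1.64, and the unfolded protein and integrated stress response (0.08), with Chac1 at 0.61. Drug metabolism (median 0.12) had 6 higher and 4 lower adjusted over the list alone and 0 calls over all genes, and the aryl hydrocarbon receptor list had a median of -0.00 and a mean of 0.54, with Cyp1a2 as its call. Also not called were the interferon response (-0.19), with Gbp2 at -0.79, oxidative phosphorylation (0.01), with Sdhd at 0.45, ribosomal proteins (0.05), with Rps19 at -0.20, endothelial markers (-0.21), with Lyve1 at -0.76, and exocrine pancreas markers (0.22), with Cela1 at 0.46. Male-biased genes had a median of 0.02 over both times, -0.25 at ZT2 and 0.39 at ZT14, with Hsd3b5 at -0.69 and Cyp4a12a at 0.72, and female-biased genes had a median of 0.37, or 0.00 with the undetected member at its bound. Clock genes high at dusk had a median of 0.19, with Nr1d2 at 0.61. The lists not tested held S100a8 at -1.33, Ccl5 at -0.85, Sox9 at -0.91, Adipoq at 0.55 and Rora at -0.10. Skeletal muscle genes had a median of -0.12 at ZT2 and -1.45 at ZT14.

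**Figure D2:**
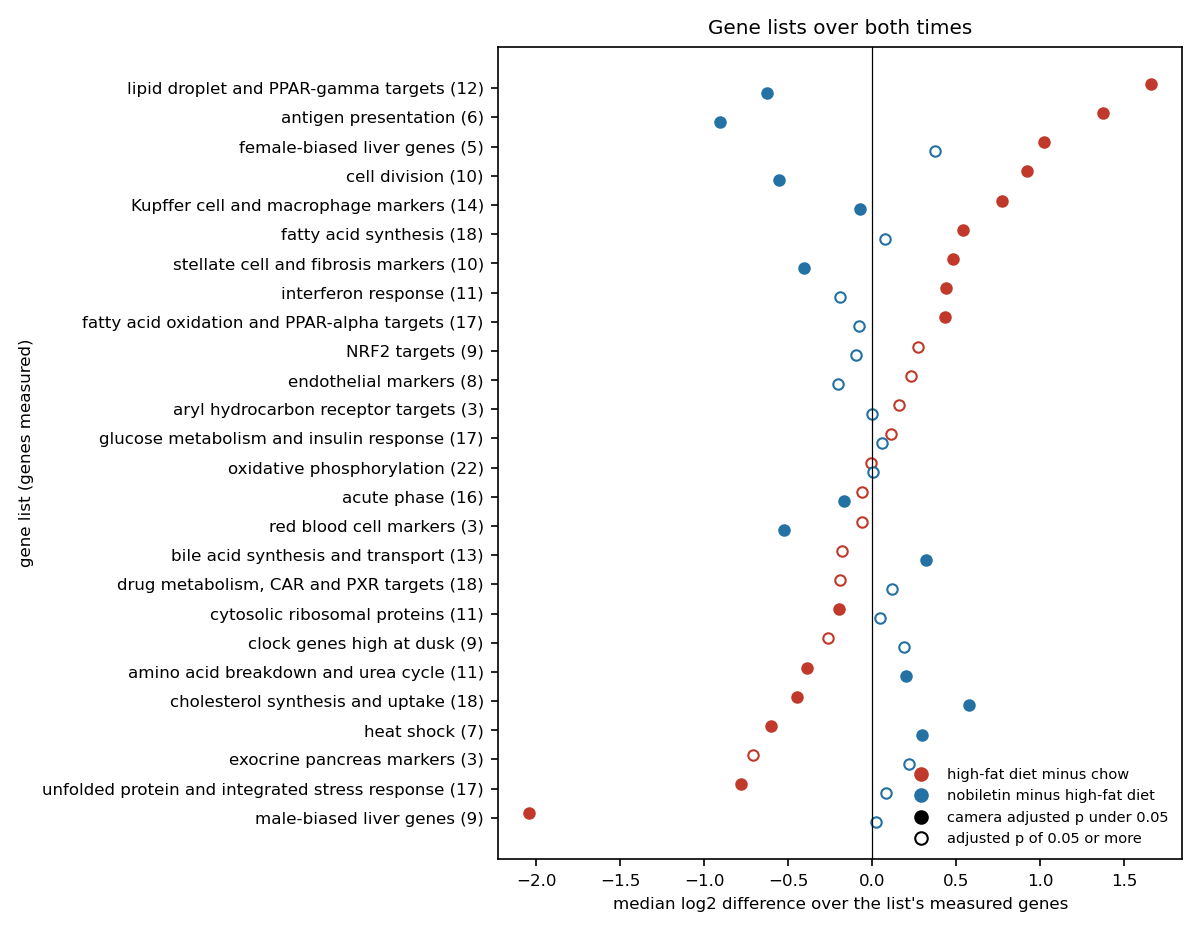
The horizontal axis gives the median log2 difference over the measured genes of each list on the vertical axis (number measured in brackets), for the high-fat diet minus chow (red) and nobiletin minus the high-fat diet (blue), and filled points had a camera adjusted p under 0.05 at the preset correlation. Lipid droplet genes lie at 1.66 and -0.63 and cholesterol synthesis genes at -0.45 and 0.58, on opposite sides of 0. Both differences share the HFD arrays, which favours opposite signs.

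With limma, 14 genes passed for nobiletin, a number that followed the arrays used. It was 0 without the HFD array of ZT2, with every named call lost, 0 without the HFD array of ZT14, 2 without the NOB array of ZT2, 18 without the NOB array of ZT14, and 41 without the RC array of ZT2 or of ZT14. Of the 9 calls named by the fixed choice, 8 were lost without the NOB array of ZT2 and 5 without that of ZT14. At single times without a test, 41 genes were at least 1.5-fold higher and 116 at least 1.5-fold lower at both times, against 19 in opposite directions, with r = 0.37 across genes.

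Of the 14 nobiletin calls, 13 were also diet calls, all 13 with the opposite sign. Both differences share the HFD arrays, which makes opposite signs likely: in simulated arrays with no effect 0 genes passed both, and 9 of the 9 genes shared by the 585 and 14 of smallest p were opposite. The exception was Orm2, at 0.58 for the diet (adjusted p = 0.0683). Cyp1a2, Igfbp2 and Upp2 fell on the diet and rose with nobiletin, and Gpnmb, Lcn2, Ubd, Sdcbp2, Timp1, Anxa2, S100a11, Cbr3, Limk1 and Slc13a4 rose on the diet and fell with nobiletin. Among the 585 diet calls, 530 (90.6%) had the opposite sign under nobiletin, against 88.9% of as many genes of smallest p in the simulated arrays. Those arrays held no diet difference, so their genes were picked by noise alone. The share expected for genes with a real diet difference was not simulated. The comparison therefore cannot tell how much of the 90.6% comes from the shared arrays.

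To avoid the shared arrays, diet differences at 1 time were set against nobiletin differences at the other. Of 1147 genes at least 1.5-fold apart on the diet at ZT2, 772 had the opposite nobiletin sign at ZT14 (67.3%, 95% interval 64.5% to 70.0%), against 56.1% of all genes. Of 1633 genes chosen at ZT14, 1278 were opposite at ZT2 (78.3%, 76.2% to 80.2%), against 62.6% of all genes. The crossed differences correlated at r = -0.31 and r = -0.46 across genes. With the HFD array shared, the shares were 89.0% at ZT2 and 80.1% at ZT14, against 86.3% simulated with no effect. The simulation held no diet difference either, so 86.3% is no benchmark for genes that differ by diet. Cyp2b9, at 5.74 for the diet, lay at -0.44 for nobiletin and did not pass.

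Between nobiletin on the high-fat diet and chow, 45 genes were higher and 40 lower (limma, 1285 at an unadjusted p under 0.05). Of the 585 diet calls, 78 also passed this comparison in the same direction, Cyp2b9 and Apoa4 among them, at 5.30 and 5.21. Both comparisons share the RC arrays, which favours the same direction, and no value without sharing was computed. The 85 calls became 170 without the RC array of ZT2, 35 without that of ZT14, 19 without the HFD array of ZT2 or of ZT14, 46 without the NOB array of ZT2 and 18 without that of ZT14.

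The comparison of ZT14 with ZT2 asked which genes followed the time of day. Over the 3 arms, 2 genes rose from ZT2 to ZT14. Thrsp, a lipogenic protein of the liver, was 4.49-fold higher at ZT14 (2.17 ± 0.16, adjusted p = 0.0127), at 2.46 in RC, 2.25 in HFD and 1.79 in NOB. The other probe of Thrsp lay at 0.13, so the call rests on the brighter probe. Tnnc1, a troponin of slow and cardiac muscle, was 3.61-fold higher (1.85 ± 0.13, adjusted p = 0.0127), at 2.02 in RC, 1.95 in HFD and 1.59 in NOB, where it was undetected at ZT2. Skeletal muscle transcripts were high in the RC and HFD pools of ZT14, and muscle carried over at dissection was not tested. Genes at least 2-fold apart in every arm that did not pass were Nrg4 at 1.79, Per2 at 1.64, Lingo4 at 1.49, the elongase Elovl6 at 1.23, Hectd2os at -2.59, the growth hormone-induced Socs2 at -1.81, Chac1 at -1.69 and Nr1d1, which encodes the repressor REV-ERB alpha, at -1.78 (at least 2.40-fold).

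Fatty acid synthesis genes lay higher at ZT14, with Thrsp as the call among 18 and 9 higher adjusted over the list alone, Elovl6 at 1.23 and Pnpla3 at 0.86 (camera adjusted p = 3.51e-07, and adjusted p = 0.556 with an estimated correlation). Unfolded protein and integrated stress response genes lay lower, with 0 of 17 calls, or 3 adjusted over the list alone, Chac1 at -1.69 and Calr at -1.04 (camera adjusted p = 1.31e-05, and adjusted p = 0.556 with an estimated correlation). Their median was 0.07 in RC, -0.62 in HFD and -0.67 in NOB, so it was not lower on chow. Arms differed for other lists too, without a test: fatty acid synthesis had medians of 0.13, 0.50 and 0.44 in RC, HFD and NOB, and lipid droplet genes of 0.36, 0.02 and 0.61. Lipid droplet genes lay higher with 5 calls adjusted over the list alone and 0 over all genes, Plin4 at 1.49 (camera adjusted p = 0.00575, and adjusted p = 0.605 with an estimated correlation). The call ended without the RC array of ZT2 (adjusted p = 0.0678) and without that of ZT14 (adjusted p = 0.0694). Its range was 6.14e-05 to 0.605 over the alternatives. Smaller list shifts were each ended by leaving out arrays and had 0 calls over all genes. For time, leaving out either array of an arm gives the same fit, so losses within an arm are not separate results. Their medians in RC, HFD and NOB were 0.18, -0.02 and 0.22 for fatty acid oxidation, -0.01, 0.12 and 0.13 for oxidative phosphorylation, -0.20, -0.64 and -0.09 for male-biased genes, and -0.95, 0.06 and -0.50 for red blood cell markers. Fatty acid oxidation, with Acot1 at 0.88 and 2 calls adjusted over the list alone, lay higher (camera adjusted p = 0.0238, and adjusted p = 0.605 with an estimated correlation). This one ended without the NOB array of ZT2 (adjusted p = 0.144) or of ZT14 (adjusted p = 0.123). Its range was 0.00720 to 0.605 over the alternatives. Oxidative phosphorylation lay higher (camera adjusted p = 0.0388, and adjusted p = 0.605 with an estimated correlation). This call ended without the HFD array of ZT2 (adjusted p = 0.260) or of ZT14 (adjusted p = 0.276) and without the NOB array of ZT2 (adjusted p = 0.159) or of ZT14 (adjusted p = 0.134). Its range was 0.00673 to 0.605 over the alternatives.

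Drug metabolism, with Cyp2b10 at 1.08, lay higher at ZT14 (camera adjusted p = 0.0414, and adjusted p = 0.556 with an estimated correlation). Drug metabolism was not called without the HFD array of ZT2 (adjusted p = 0.110) or of ZT14 (adjusted p = 0.130) or the RC array of ZT2 (adjusted p = 0.135) or of ZT14 (adjusted p = 0.144). Its range was 0.00922 to 0.556 over the alternatives. The acute phase, with Mt1 at 0.87 and Saa2 at 0.76, lay higher (camera adjusted p = 0.0414, and adjusted p = 0.556 with an estimated correlation). The acute phase was not called without the HFD array of ZT2 (adjusted p = 0.132) or of ZT14 (adjusted p = 0.145) or the NOB array of ZT2 (adjusted p = 0.0547) or of ZT14 (adjusted p = 0.0502). Its range was 0.0300 to 0.556 over the alternatives. Male-biased genes lay lower (camera adjusted p = 0.0268, and adjusted p = 0.605 with an estimated correlation). Among them Hsd3b5 lay at -1.97, a size that rests partly on background. Its levels at ZT14 were 4.37 in HFD and 4.34 in NOB, under the lowest detected levels of those arrays, 5.04 and 5.08. In RC, Hsd3b5 lay at 11.06 at ZT2 and 10.87 at ZT14. Male-biased genes were not called without the HFD array of ZT2 (adjusted p = 0.505) or of ZT14 (adjusted p = 0.530). Its range was 0.000666 to 0.605 over the alternatives. Red blood cell markers, with Hba-a1 at -0.46, lay lower (camera adjusted p = 0.0315, and adjusted p = 0.605 with an estimated correlation). Red cell markers were not called without the RC array of ZT2 or of ZT14 (adjusted p = 0.231 for each) or the NOB array of ZT2 (adjusted p = 0.0794) or of ZT14 (adjusted p = 0.0685). Its range was 0.000802 to 0.605 over the alternatives. The other lists gave no camera call for time: cholesterol synthesis (median 0.18), bile acids (-0.11), glucose metabolism (0.01), aryl hydrocarbon receptor targets (-0.02), the interferon response (-0.03), amino acid breakdown (-0.02), female-biased genes (0.38), cell division (0.14), ribosomal proteins (0.05), antigen presentation (0.05), stellate cell markers (0.17, or 0.11 with the undetected member at its bound), endothelial markers (-0.07) and exocrine pancreas markers (-0.02). Signs differed for NRF2 targets (median -0.14, mean 0.02, test direction higher), heat shock (median 0.00, mean -0.000468, test direction higher) and macrophage markers (median 0.01, mean -0.02, test direction lower), none of them called. The macrophage list turned and passed as higher without the RC array of ZT2 (adjusted p = 0.0109) or of ZT14 (adjusted p = 0.0115), and passed as lower without the NOB array of ZT2 (adjusted p = 0.0205) or of ZT14 (adjusted p = 0.0186), in a range of 0.0109 to 0.898.

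Clock genes differed between the arms in their day-night change, as values from single arrays. Nr1d1 was detected at ZT2 and on 0 of the 3 arrays of ZT14, so that its changes within arms have no measured size. Per2, a repressor of the clock, was higher at ZT14, at 2.58 in RC, 1.18 in HFD and 1.17 in NOB. Dbp, an output transcription factor of the clock, was 0.57 higher at ZT14 in RC but lay at -2.02 in HFD and -1.63 in NOB. Arntl, which encodes the clock activator BMAL1, lay at -1.03 in RC, 0.90 in HFD and 0.42 in NOB. Ciart was 2.16 higher at ZT14 in RC and lay at -0.03 in HFD and -0.25 in NOB. In RC the others lay at 0.45 for Nr1d2, 1.31 for Tef, 1.26 for Per1, 0.94 for Cry2, 1.04 for Bhlhe40 and -0.10 for Clock. HFD gave -1.31 for Nr1d2, 0.10 for Tef, 0.21 for Per1, 0.53 for Cry2, 0.60 for Bhlhe40 and -0.37 for Clock. NOB gave -0.72, 0.28, 0.24, 0.30, 0.31 and -0.19 in the same order. Between HFD and RC the 9 measured dusk genes had a median of 0.55 at ZT2, above 99.95% of random lists matched on expression, and of -0.66 at ZT14, below all of them. These ranks compare single arrays and carry no error between pools, so they do not test a difference between the arms. Over both times 0 of the 9 passed limma for the diet, nobiletin or time, where 3 were higher and 1 lower at ZT14 adjusted over the list alone (camera adjusted p = 0.606 for the diet, 0.0986 for nobiletin and 0.120 for time, and adjusted p = 0.898, 0.754 and 0.754 with an estimated correlation). Without the RC array of ZT2 the dusk list passed as lower for the diet (adjusted p = 0.000171), and without that of ZT14 it turned and passed as higher (adjusted p = 0.00188), in a range of 0.000171 to 0.898 over its alternatives. The dawn list held 2 measured genes and was not tested.

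**Figure D3:**
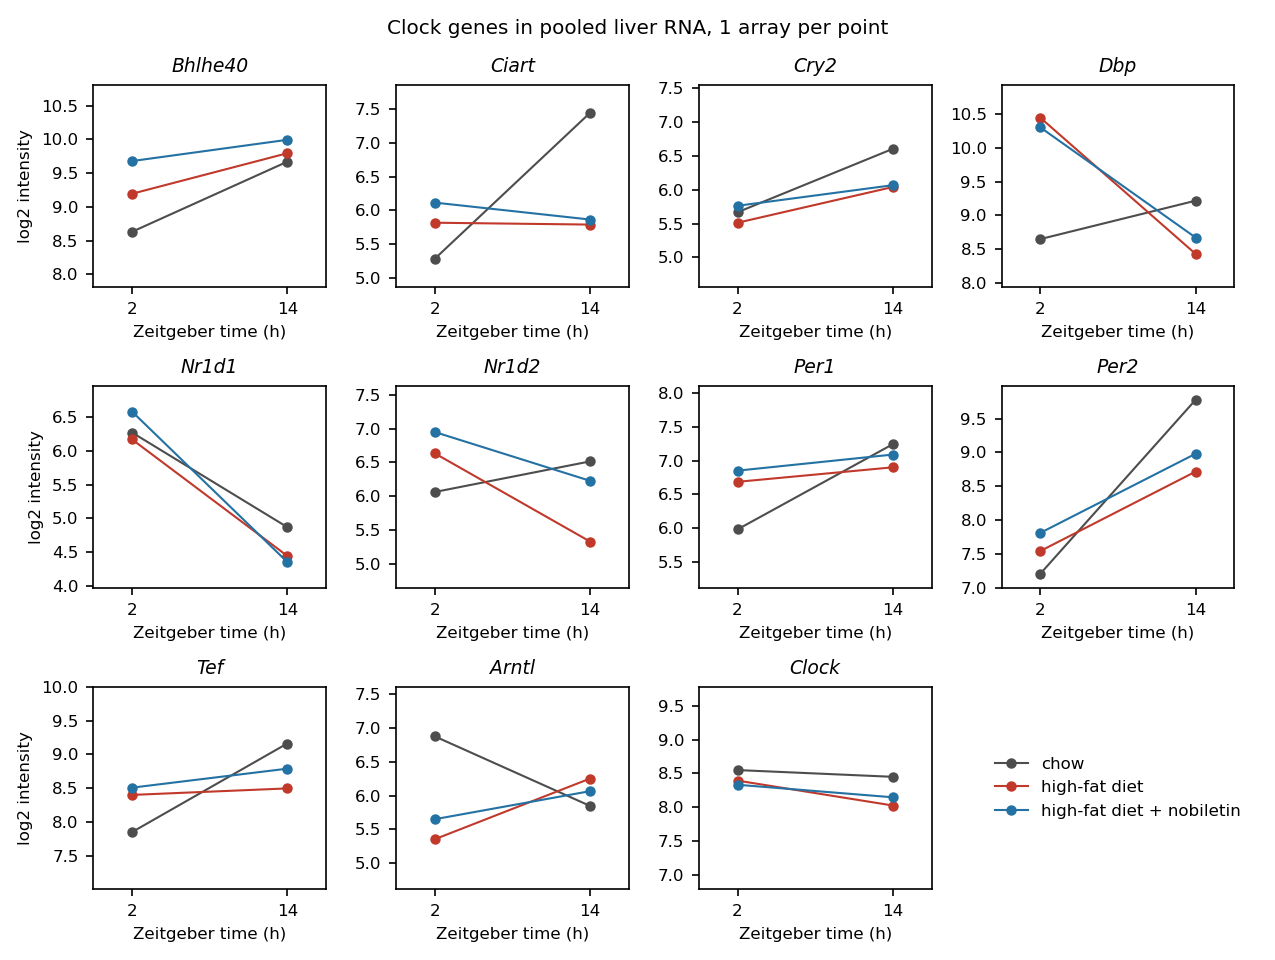
Each panel plots the log2 intensity of a clock gene against zeitgeber time in hours, with 1 array per point and lines joining the arrays of chow (grey), the high-fat diet (red) and the high-fat diet with nobiletin (blue). Dbp differs by 0.57 between ZT2 and ZT14 on chow against -2.02 and -1.63 on the high-fat diet without and with nobiletin, and Arntl by -1.03 against 0.90 and 0.42, while Nr1d1 was undetected at ZT14.

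Counted within single arms without a test, 172 genes were at least 2-fold apart between the times in RC (93 higher at ZT14), 101 in HFD (69 higher) and 104 in NOB (65 higher). Of these, 10 were apart the same way in all 3 arms, 6 higher and 4 lower. Transcripts of skeletal muscle were high in the RC and HFD pools of ZT14, but not in NOB. Of 14 measured muscle genes, 12 were at least 2-fold higher at ZT14 in RC, 8 in HFD and 0 in NOB, with medians of 3.19, 1.35 and 0.06. The skeletal actin gene Acta1 went from undetected, at 4.98, to 10.12 in RC. Muscle carried over at dissection was not tested, so the counts between times may include it. Without these 14 genes the counts were 160, 93 and 104, which still include muscle transcripts outside the list, such as Tnnc1.

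**Figure D4:**
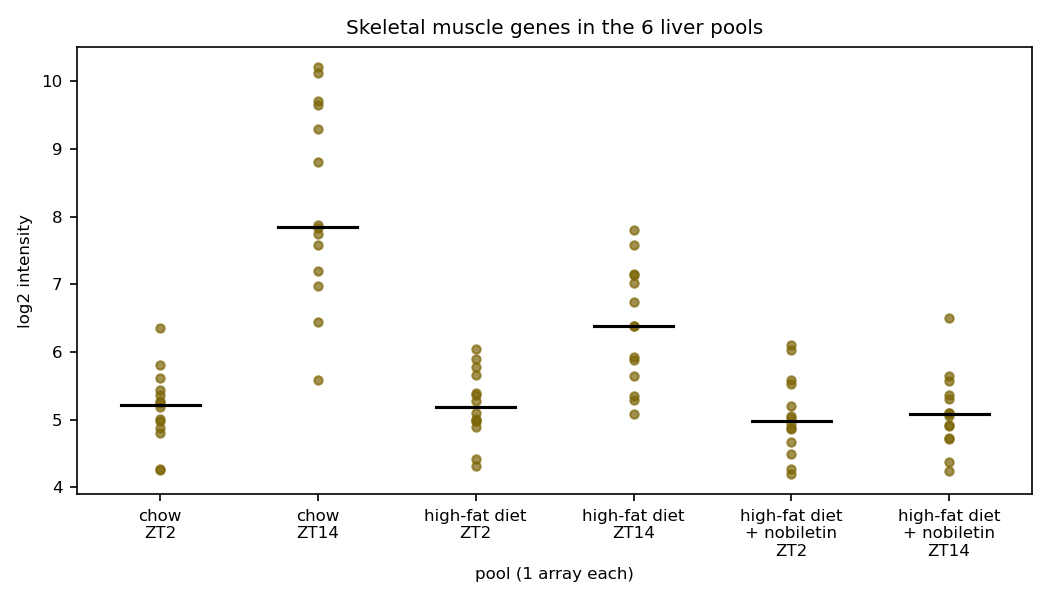
Points give the log2 intensity of 14 skeletal muscle genes in each of the 6 pools on the horizontal axis (1 array each), and black lines give the median. The median is 7.85 in chow at ZT14 and 6.38 in the high-fat diet at ZT14, against 4.98 to 5.22 in the other pools.

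The time test with limma gave 2 calls, and 933 genes lay at an unadjusted p under 0.05. For this test, leaving out either array of an arm gives by construction the same fit to the other 2 arms. Leaving out either RC array gave 11 calls, either NOB array 6 and either HFD array 1, and both Thrsp and Tnnc1 were lost without either HFD array.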

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

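The tests of the normalization and of an earlier phase for the clock genes, and those of the shared HFD arrays and of the macrophage share, were chosen only after the results they measure were seen. The genes in the next 2 paragraphs drew attention because their differences at ZT2 and at ZT14 had opposite signs. With 1 array per group, none of these differences between times was tested.

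Clock genes differed between the arms in their day-night change. The HFD minus RC difference at ZT2 exceeded that at ZT14 by 2.59 for Dbp, 2.19 for Ciart, 1.76 for Nr1d2, 1.40 for Per2, 1.22 for Tef and 1.05 for Per1, and it lay below it for Arntl, at -1.93. An array with the wrong time is argued against, since 68.0% of the genes at least 2-fold apart in RC went the same way in NOB and 82.6% did in HFD. For Dbp the normalization made here is argued against too. Its value stayed at 2.42 under the less favourable of the authors' values and no background correction. Both of these were quantile normalized, and median scaling, without that step, gave 2.49 for Dbp. With an offset of 50 Nr1d2 gave 1.04, Ciart 1.39, Per1 0.70 and Arntl -1.16, with unchanged signs. An earlier phase in the HFD pools may be involved, with 7 of 10 clock genes going its way at both times (not Cry2, Bhlhe40 or Nr1d1, which was undetected at ZT14), but these 7 are the genes listed here, so the count is no independent evidence. Damped rhythms predict most of these signs as well, though not by themselves the reversed day-night change from RC to HFD of Dbp (0.57 to -2.02), Nr1d2 (0.45 to -1.31) and Arntl (-1.03 to 0.90), and with 1 array per group and time both stay open.

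Other genes with opposite signs at the 2 times were single values whose difference between times was not tested. For HFD minus RC, Cyp2a4 lay at -1.50 at ZT2 and 2.31 at ZT14, a difference of -3.81. For NOB minus HFD, Cyp4a12b went from -2.19 to 1.20 (difference -3.39), Ppp1r3g from -1.33 to 1.56 (-2.89), Cyp4a12a from -0.60 to 2.04 (-2.64), Asns from -1.62 to 0.80 (-2.41) and Mt1 from -0.69 to 0.76 (-1.45). Hectd2os went the other way, from 0.62 to -1.69 (2.31). Cyp4a12b, Asns and Ppp1r3g were undetected on at least 1 of the arrays compared, so their sizes rest on background there.

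Many diet differences had the opposite sign under nobiletin. The HFD arrays enter both differences and give opposite signs on their own, yet with no array shared the share of opposite signs was 67.3% for genes chosen at ZT2, against 56.1% of all genes, and 78.3% for genes chosen at ZT14, against 62.6%. The authors' values gave 67.1% for genes chosen at ZT2, against 56.3% of all genes, and 77.9% for genes chosen at ZT14, against 62.8%. Those values were also background-subtracted and quantile normalized, so they cannot separate these steps from the result. Median scaling, without quantile normalization, gave 65.2% and 77.5%, with no share over all genes to set beside them. A lower share of macrophages as a whole is argued against for the macrophage genes. The 9 resident and pan-macrophage genes had medians of -0.15 at ZT2 and 0.42 at ZT14, where Gpnmb, Trem2 and Lgals3 had medians of -1.16 and -1.35. Fewer lipid-laden macrophages alone could give the same medians, so that stays open beside lower expression per cell. The shares of opposite signs could come from a weaker response to the diet for part of the genes. Fatty acid synthesis (0.05 at ZT2 and 0.12 at ZT14) and the unfolded protein response (0.18 and 0.07), however, had small medians for nobiletin. Male-biased genes went opposite ways (-0.25 and 0.39). Less exposure to the diet through lower food intake or weight, which are not given in the sources used here, stays open as untested.

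Male-biased genes were lower on the high-fat diet, with a median of -2.04. HFD pools made up mostly of female mice are argued against, since Eif2s3y lay between 7.64 and 8.12 on all 6 arrays. The largest difference of a Y-linked gene from RC was 0.60, for Uty in NOB at ZT2, close to background. Of the Xist probes 0 were detected on any array, which says little without an array known to hold Xist. A minority of female mice in a pool stays open. A lower share of hepatocytes is argued against, since the median of 15 hepatocyte genes was -0.13 at ZT2 and 0.00 at ZT14, and 5 of them between background and the top of the scale had medians of -0.28 and -0.06, while Alb, also among the 15, lay near background at 4.77 to 5.39 and says little. Igf1, Igfals, Socs2, Cish and the receptor gene Ghr had a median of -0.58, which is consistent with weaker growth hormone signalling as a hypothesis, with Socs2 at -1.13 (limma adjusted p = 0.0464) and Ghr at 0.04. Hormone levels are not given in the sources used here.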

How the results depend on the processing

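The test of every detected probe and the counts without skeletal muscle genes were chosen only after the results were seen. Among named genes no result that passed turned in sign. With 1 array left out, 6 to 10 of 78 list directions turned for each array, as did 4 of 72 with detection on all 6 arrays and 4 of 78 with no detection filter. Those that passed before or after a leave-out were macrophage markers (NOB minus HFD, without the NOB array of ZT2, adjusted p = 0.825 in a leave-one-out range of 1.40e-05 to 0.825) and heat shock (the same array, 0.598 in 6.69e-06 to 0.598). Others were macrophage markers over time (without the RC array of ZT2, 0.0109, or of ZT14, 0.0115, in 0.0109 to 0.439) and dusk clock genes for the diet (without the RC array of ZT14, 0.00188, in 0.000171 to 0.633). Under the authors' values 523 of the 585 diet calls, 14 of 14 for nobiletin, 85 of 85 for NOB minus RC and 2 of 2 for time still passed, all with the same sign, and all 78 list results kept their side of the threshold. Under median scaling 499, 14, 77 and 2 still passed, under an offset of 50 these were 483, 12, 69 and 1, and without background correction 491, 12, 70 and 1. Of 288 gene results, 287 kept their side of the threshold under the authors' values and 280 under median scaling.

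Background handling set the counts by fold. An offset of 50 gave 351 genes at both times for the diet, 85 for nobiletin, 82, 41 and 59 between times in RC, HFD and NOB, and crossed shares of 70.6% and 81.5%. No background correction gave 362, 89, 83, 46, 61, 70.6% and 80.9%. Both alternatives compress differences near background by construction. A 2-fold threshold gave 205 and 43 genes at both times and shares of 74.7% and 84.7%, and a 1.5-fold threshold gave 804, 463 and 608 genes between times.

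Test counts moved more, and the cause was not tested unless stated. Without a detection filter 88, 1, 1 and 0 genes passed for the diet, nobiletin, NOB minus RC and time, where limma had 933 genes at an unadjusted p under 0.05 for time with the filter. Detection on all 6 arrays gave 9 for nobiletin and 9 for time, the mean of probes 1 for time, and median scaling 6 for time. An intensity trend with robust moderation gave 39, 172 and 36 for nobiletin, NOB minus RC and time. Fitting only the 2 arms compared gave 41 and 19 for nobiletin and NOB minus RC, no term for time 303, 9 and 13 for the 3 arm contrasts, and no term for arm 0 for time. Testing every detected probe gave 907, 25, 159 and 21, from 14416 probes tested in place of 8561 genes. With an estimated correlation 0 of 35 list shifts remained called.

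Leaving out 1 array gave 32 to 734 genes for the diet, 0 to 41 for nobiletin, 18 to 170 for NOB minus RC, 1 to 11 for time and 27 to 39 list shifts. An arm then has a lone array, which is assumed to vary like the others. Leaving out an RC array fits nobiletin from HFD and NOB alone, which by construction gives the 41 of the fit to the 2 arms. Leave-one-out gave no value for counts at single times, counts between times within an arm or crossed shares, since each group has 1 array. No paired analysis was possible because each liver was taken once, so that no mouse was measured at both times or in 2 arms. Thrsp ranged from 1.15 to 2.36 and Tnnc1 from 1.09 to 1.98 over their alternatives, with adjusted p of 0.00123 to 0.313 and 0.0035 to 0.499 with limma. Signal over background limits the low end: genes undetected in a group, such as Fgf21 in RC, have folds only as lower bounds, and genes under detection on 5 or more arrays entered only the counts without a detection filter and the reading of Xist.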

Other observations

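The skeletal muscle and brown fat lists and the genes with opposite signs at the 2 times were chosen only after results were seen, while the split of the arrays by time was planned. Values of growth hormone response genes for the diet and for nobiletin share the HFD arrays, which favours opposite signs. Socs2, a feedback inhibitor of the receptor, lay at -1.13 for the diet and 0.85 for nobiletin, Cish at -1.06 and 0.55, the circulating growth factor Igf1 at -0.58 and 0.19, and the receptor gene Ghr at 0.04 and -0.06. For nobiletin Cish lay at 1.03 at ZT2 and 0.06 at ZT14. Of these genes only Socs2 passed limma for the diet (adjusted p = 0.0464), and none of these genes passed for nobiletin.

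A few other genes, picked for opposite signs at the 2 times, are single values without a test. Egr1, a transcription factor of acute stimuli, lay at -0.66 for the diet at ZT2 and 2.71 at ZT14, and the phosphatase Dusp1 lay at -0.87 and 0.60. The hepcidin gene Hamp2 lay at -1.18 and 1.32 for the diet and at 1.55 and -1.59 for nobiletin, while Hamp lay at -1.75 and -1.47 for the diet, the same way at both times. Lpin1, a phosphatidate phosphatase of lipid synthesis, lay at 0.67 and -0.91 for the diet. For nobiletin the taurine synthesis gene Csad lay at -0.97 and 0.91 and the acyltransferase Acnat2 at 0.80 and -1.70.

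Transcripts of brown fat varied too. Ucp1, the uncoupling protein of brown fat, lay at 0.93 for nobiletin at ZT2 and -1.74 at ZT14, and Cox8b lay at 0.82 and -1.19. The 6 measured brown fat genes had medians of 0.37 and -0.94 for nobiletin at the 2 times. Ucp1, Cox8b, Cox7a1, Fabp3 and Cpt1b were highest in the RC and HFD pools of ZT14, where skeletal muscle transcripts were also high. Ucp1 lay at 7.10 in RC, 6.96 in HFD and 5.22 in NOB at ZT14. At ZT2 it lay at 6.15, 5.80 and 6.74 in the same order. Ppargc1b was instead highest in NOB at ZT2, at 7.36. Tissue carried over at dissection was not tested, so the nobiletin differences of brown fat genes may include it. Among detected probes without a single gene name, 102 of 1931 passed for the diet, 3 for nobiletin, 28 for NOB minus RC and 5 for time.

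For the 2 genes that passed for time, the 6 arrays allow 10 splits into 3 and 3, of which 1, the real one, gave as many. The real split gave 2 genes and the highest of the others gave 0, and 10 splits can never give a share under 0.05. Most of the other splits put both arrays of an arm on the same side. Their difference then rests on a single arm, which makes calls less likely, so they are not like the real split.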
